A study of Mus musculus with 18 samples.

How the data were processed

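RNA was measured in 18 cultures of PyMT-BO1 cells, a mouse luminal B-like breast cancer line from C57BL/6 mice in which integrin β3 had been knocked out. The cells carried an empty retroviral vector (pMx), a functional human integrin β3 (hβ3) or a mutant integrin β3 without signalling function (Δβ3). Each line received DMSO or 10 nM docetaxel for 24 h, in 3 cultures per group. Per the labels, libraries were made from 1 µg of total RNA after removal of ribosomal RNA by hybridisation, with random hexamer priming and 13 PCR cycles, and were read as single 50-base reads.

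The deposited table holds the authors' raw read counts, made with FastQC, HISAT2 and featureCounts on the mouse build mm10 per the labels. Tool versions, the annotation, the strand setting and the handling of reads that fit several places or several transcript models are not given in the sources used here. The deposited table also gives the length of each transcript model in bases, a unit of its own that was used for counts per kilobase in 1 check and in no test. The table has 63759 transcript models for 32699 gene symbols. Counts of all models with the same symbol were summed, which concerned 13170 symbols. Symbols were matched to the GENCODE M21 annotation of mm10 for coordinates, and 10331 of the 12145 tested symbols had a match.

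Reads shared by several models of a gene may be missing from the counts, and the values do not settle for which genes. Among the listed genes that were not tested, Canx, Lamp1, Sparc and Xbp1 had 0 counts in total. The heart muscle markers Tnnt2 and Mb had 0 counts in Δβ3 docetaxel culture 2, where all heart muscle markers together had 299905. A gene with few or no counts is therefore not shown to be silent. Among housekeeping genes, the median was 47840 counts per kilobase for symbols with 1 model and 468.9 for symbols with 2 models. It was 404.7 for 3 models, 187.2 for 4 and 78.6 for 5 or more. Over all protein-coding symbols the medians showed no such fall, at 32.7 for 1 model, 28.2 for 2, 19.9 for 3, 28.8 for 4 and 39.0 for 5 or more. Levels of different genes are not compared.

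Tests used R 4.3.3 and edgeR 4.0.16. Genes were kept by the filterByExpr function with the 6 groups, scaled with TMM factors and tested with the robust quasi-likelihood F-test in 1 design with a coefficient per group over all 18 libraries. The tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were docetaxel against DMSO as the mean of the 3 lines and within each line, the 3 differences between lines in that response (interactions) with a joint test of them, and the 3 pairs of lines in DMSO and in docetaxel. Log2 fold changes are given with their standard error (SE) and levels as counts per 1e6 counts of the scaled library size (CPM) with the standard deviation (SD) over 3 cultures. The 95% interval of a log2 difference comes from its edgeR SE under a normal approximation, and that of a correlation from 1000 bootstraps over genes.

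Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the first set of alternative settings. There were 25 lists. Of these, 21 had at least 5 tested members and were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted within each comparison. The tested lists were p53 targets, G2/M and mitosis, DNA replication and S phase, tubulins, drug efflux transporters, interferon response, NF-kB and secreted inflammatory factors, sterol synthesis, amino acid and ATF4 response, endoplasmic reticulum chaperones, oxidative stress (NRF2 targets), integrins, extracellular matrix and mesenchymal genes, SRF and YAP targets, immediate-early and MAPK output genes, the BCL2 family, glycolysis and hypoxia, lysosome, nuclear genes of oxidative phosphorylation, luminal epithelial markers and fibroblast markers. The lists of basal and myoepithelial, leukocyte and macrophage, and endothelial markers had 4 tested members each and were not tested. None of the 13 genes of the mitochondrial genome was in the table. The call of each list was repeated with an estimated correlation and with fry, which asks whether the genes of a list move 1 way on balance.

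Named genes were protein coding, called, with a mean of at least 2 CPM over the compared groups and CPM ranges that did not overlap between the compared groups (for the mean response, in each line; not asked of interactions). From these, the largest changes were taken, 12 in each direction for the mean response, 3 for each line, 6 for each interaction, 8 for lines in DMSO and 3 for lines in docetaxel. Added to them were up to 4 members of each described list with the smallest p, and a set named in advance (Itgb3, Itgav, Itga2b, Cdkn1a, Mdm2, Abcb1a, Abcb1b, Tubb3, Ccnb1, Mki67, Actb, Gapdh). Other genes that appear in the text were chosen after their values were seen, and the text says so. Some genes that met the rule are not reported here.

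The first set was DESeq2 1.42.0 with its own size factors, RLE factors, no filter on low counts, a filter at 1 CPM in 3 libraries, a replicate block, a fit of only the compared groups, and leaving out each library of the compared groups. Alternatives chosen after the data were seen were a fit of 16 libraries without Δβ3 DMSO culture 1 and Δβ3 docetaxel culture 2, the same fit with the heart transcript level as a covariate, counts without Rn45s, leaving out each library of the other groups, and tests of single transcript models. The 16-library fit tested 12356 genes.

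The tests were checked on simulated data with known changes, in which every library had the spread fitted over all libraries of the fit. The 18-library spread includes the 2 cultures left out of the 16-library fit. Its rates therefore need not hold for lines without such cultures. For the mean response, edgeR recovered 67.2% of genes changed 2-fold and 19.4% of those changed 1.5-fold. For docetaxel in pMx it recovered 11.9% at 2-fold and 50% at 4-fold, and for an interaction 4.48% at 2-fold and 33.3% at 4-fold. With 16 libraries these became 73.1% and 50.8%, 55.2% and 77.3%, and 38.8% and 66.7%. Unchanged genes made up 0% to 6.82% of edgeR's calls over 18 libraries, 2.34% to 11.7% of those over 16, and 10.96% to 17.3% of DESeq2's calls over 18.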

Results

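Gene expression was measured by RNA sequencing in 18 cultures of integrin β3 knockout PyMT-BO1 breast cancer cells, 3 for each of 3 lines (empty vector pMx, functional human hβ3, signalling-deficient Δβ3) in DMSO and in 10 nM docetaxel, a taxane that stabilises microtubules. Total counts per library, in units of 1e6, ran from 7.97 to 18.96, with a mean of 13.2 ± 3.36 (SD, n = 18). The group means in the same units were 12.7 in pMx DMSO, 11.7 in pMx docetaxel, 12.8 in Δβ3 DMSO, 10.96 in Δβ3 docetaxel, 17.6 in hβ3 DMSO and 13.3 in hβ3 docetaxel (n = 3 each). The 3 cultures of a group come from 1 line per construct, so the p-values measure the spread between cultures, and a difference between lines holds everything that sets those lines apart.

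Itgb3, which encodes integrin β3 (chromosome 11, 104608000 to 104670476, plus strand, mm10), separated the empty vector line from both rescued lines. It had 0.965 CPM ± 0.557 (SD, n = 3) in pMx DMSO, 96.6 ± 26.0 in Δβ3 DMSO and 108.5 ± 31.7 in hβ3 DMSO. In docetaxel it had 0.633 CPM ± 0.210, 84.7 ± 44.9 and 107.4 ± 10.2 in the same order. The pMx libraries held 5 to 20 Itgb3 counts each. The hβ3 construct is human per the labels, the species of Δβ3 is not given in the sources used here, and the reads were counted on the mouse genome. Reads from a human sequence count only where they align to mouse Itgb3, so these values do not measure the amount of construct RNA and hβ3 and Δβ3 are not compared for it.

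Transcripts of heart muscle were measured in every library. The summed level of 22 heart muscle markers, among them Tnni3, Myl2 and Actc1, was 46610 CPM in Δβ3 docetaxel culture 2 and 5543 CPM in Δβ3 DMSO culture 1. In the other 16 libraries it lay between 186.8 and 2341 CPM. The highest of these were all in pMx, at 2341 CPM in docetaxel culture 1, 2059 in DMSO culture 1 and 1383 in DMSO culture 2. The 16-library fit therefore still holds uneven heart transcript levels. Rn45s, the precursor of ribosomal RNA, took 41.5% of counts in Δβ3 DMSO culture 1, 23.6% in Δβ3 docetaxel culture 2, 10.9% to 33.0% in the hβ3 DMSO libraries and 6.59% to 9.81% in the pMx libraries. In Δβ3 docetaxel culture 2, Itgb3 had 32.9 CPM, against 113.5 and 107.6 CPM in cultures 1 and 3 of that group. Krt8, a luminal epithelial marker chosen after its values were seen, was lower there as well. It took 0.0633% of the counts outside Rn45s in culture 2, against 0.226% and 0.235% in cultures 1 and 3. The biological coefficient of variation was 36.1% over all 18 libraries and 13.2% without these 2 cultures, so the main counts of called genes are also given for the 16 other libraries.

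**Figure D1:**
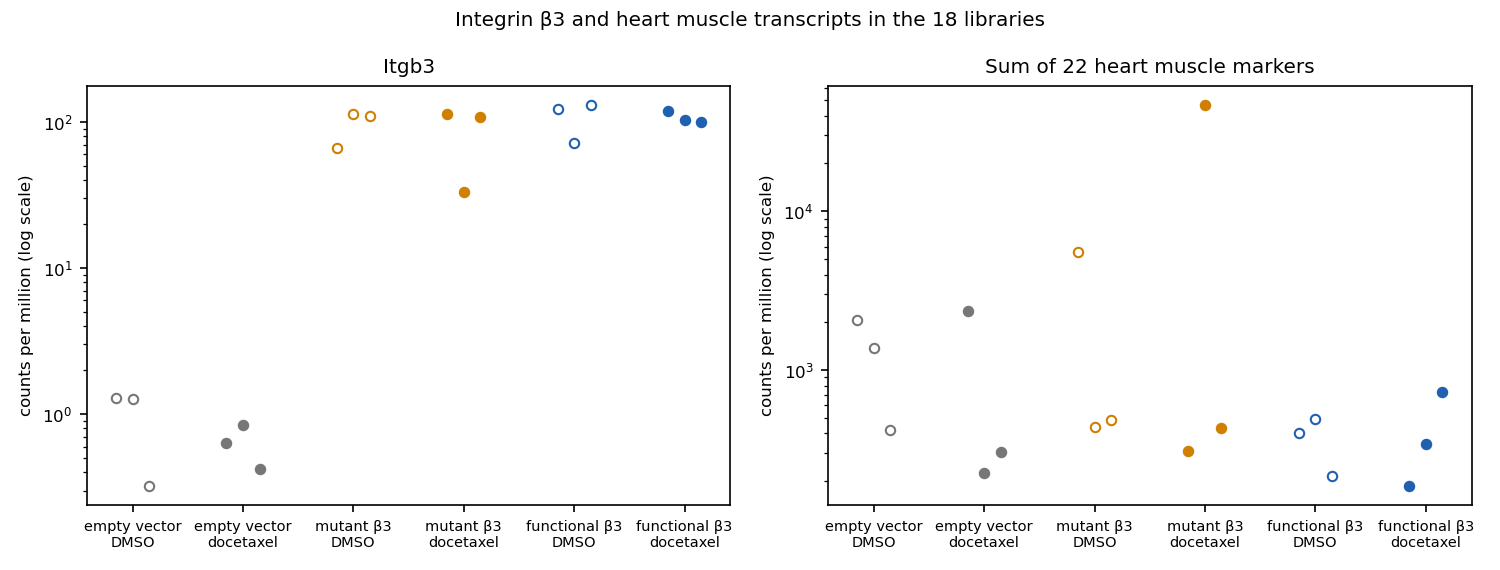
Itgb3 level (CPM, log axis) and summed level of 22 heart muscle markers (CPM, log axis) in each of the 18 libraries by group, with open circles for DMSO and filled circles for docetaxel and with pMx written as empty vector, Δβ3 as mutant β3 and hβ3 as functional β3. Itgb3 is near 1 CPM in pMx, and the heart marker sum stands at 46610 CPM in Δβ3 docetaxel culture 2 and 5543 CPM in Δβ3 DMSO culture 1.

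The first comparison asked how the cells responded to docetaxel, as the mean of the 3 lines. Interferon response genes and p53 targets rose, while most genes of DNA replication and of the amino acid and ATF4 response fell. Ifi44, an interferon-induced gene (chromosome 3, 151730922 to 151749960), rose by a log2 fold change of 2.59 ± 0.22 (SE, 9 against 9 libraries), and Usp18, which removes ISG15 from proteins and dampens interferon signalling, by 2.35 ± 0.17. Krt15, a keratin of basal epithelial cells, rose by 2.48 ± 0.22 and Fas, a death receptor and p53 target, by 1.95 ± 0.26. The largest decrease among named genes was that of Mettl7b (chromosome 10, 128958274 to 128960988), at -2.01 ± 0.11, followed by F2rl1, the receptor PAR2 for trypsin-like proteases, at -1.36 ± 0.07. Mybl2, a transcription factor of cycling cells, stood at -1.08 ± 0.07.

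In total 1891 of 12145 tested genes changed (edgeR quasi-likelihood test, adjusted p under 0.05), 960 upward and 931 downward, of which 335 and 28 changed at least 2-fold. With 16 libraries 3715 genes were called, and 1866 of the 1891 were called in both fits, all in the same direction. The adjusted p was 6.7e-07 for Ifi44, 1.4e-07 for Usp18, 4.1e-09 for Mettl7b and 4.6e-09 for F2rl1. Each of these genes had CPM ranges of DMSO and docetaxel cultures that did not overlap in any line. The naming rule required this, so it is no separate evidence. Further increases were those of Tcp11l2 (2.33 on the log2 scale), Gbp9 (2.17), a guanylate-binding protein induced by interferon, Dio2 (2.14), the enzyme that activates thyroid hormone, Slc40a1 (2.02), the iron exporter ferroportin, Ano3 (1.92) and Serpine2 (1.90), a protease inhibitor. Tpbg, an oncofetal surface protein, decreased by 1.05. The other decreases among the 12 largest were 8 histone genes between -1.02 and -1.19, whose copies are nearly identical in sequence, while Hist1h2bc rose by 2.15.

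Of 28 tested interferon response genes 24 rose and 0 fell (25 and 0 adjusted over the list alone), with a median log2 change of 1.46 (camera adjusted p = 2.4e-21, adjusted p = 0.0169 with an estimated correlation). Ifit3 rose by 2.02 ± 0.15 and Cmpk2, a mitochondrial nucleotide kinase induced by interferon, by 1.65 ± 0.14. Of 28 p53 targets 17 rose and 0 fell (19 and 1 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 6.2e-12, adjusted p = 7.3e-05 with an estimated correlation). Gdf15, a stress cytokine, rose by 2.63 ± 0.34, Btg2, an inhibitor of proliferation, by 1.71 ± 0.15, and Pmaip1, the BCL2 antagonist NOXA, by 1.43 ± 0.10. Cdkn1a, the cell cycle inhibitor p21, rose by 0.88 ± 0.20 (adjusted p = 0.00578), and Mdm2, which degrades p53, had 0.85 ± 0.42 (adjusted p = 0.203, and 0.0141 with 16 libraries). Both are counted at a few CPM from 3 and 4 transcript models.

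Of 28 genes of DNA replication and S phase 20 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 1.0e-17, adjusted p = 0.0453 with an estimated correlation). Mcm2 and Mcm3, subunits of the replicative helicase, stood at -0.72 ± 0.07 and -0.75 ± 0.08, and Ccne1, the S phase cyclin E1, at -0.87 ± 0.10. Of 25 genes of the amino acid and ATF4 response 14 fell and 2 rose (16 and 2 adjusted over the list alone), with a median of -0.56 (camera adjusted p = 3.0e-09, adjusted p = 0.0169 with an estimated correlation). Among those that fell, Phgdh (-0.73), Psat1 (-0.82) and Psph (-0.67) form the serine synthesis pathway, and Chac1 (-0.84) degrades glutathione. Of 12 tubulins 6 rose and 0 fell, the same counts adjusted over the list alone, with a median of 0.55 (camera adjusted p = 0.00042, adjusted p = 0.167 with an estimated correlation). Tubb2b rose by 1.63 ± 0.17, Tuba1a by 0.95 ± 0.16 and Tubb3, the neuronal β-tubulin, by 0.59 ± 0.09.

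Of 18 lysosome genes 7 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 9.8e-05, adjusted p = 0.231 with an estimated correlation). Gla, an enzyme of glycolipid breakdown, rose by 0.47 ± 0.08. Of 33 G2/M and mitosis genes 6 fell and 0 rose, also adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.0025, adjusted p = 0.54 with an estimated correlation). Aurkb, the Aurora B kinase, stood at -0.65 ± 0.10, Ccnb1, the mitotic cyclin, at -0.11 ± 0.13 (adjusted p = 0.631) and Mki67 at -0.16 ± 0.12 (adjusted p = 0.414). Of 23 sterol synthesis genes 4 fell and 0 rose, also adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.00042, adjusted p = 0.403 with an estimated correlation). Those 4 were Idi1, Srebf2, Stard4 and Acat2, between -0.37 and -0.52, and each lost its call when single libraries were left out.

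The other 13 tested lists were not called, and their counts are given as rises and falls, then adjusted over the list alone. Of 7 drug efflux transporters 1 rose and 1 fell (1 and 1), and Abcb1a, a P-glycoprotein gene, had 1.72 ± 0.71 (adjusted p = 0.125, and 0.0146 with 16 libraries). Of 18 NF-kB and secreted inflammatory factors 4 rose and 1 fell (6 and 2), of 14 endoplasmic reticulum chaperones 1 and 2 (1 and 3), and of 16 NRF2 targets 2 and 0 (2 and 0), with a median of -0.10 and a mean of 0.11. Of 13 integrins 3 rose and 0 fell (3 and 0), among them Itga2b, the platelet integrin αIIb, by 1.45 ± 0.29, while Itgav, the αv partner of β3, had 0.18 ± 0.12 (adjusted p = 0.355, and 0.00182 with 16 libraries). Of 25 extracellular matrix and mesenchymal genes 4 rose and 1 fell (5 and 1), of 19 SRF and YAP targets 0 and 2 (0 and 2), with a median of -0.10 and a mean of 0.03, and of 21 immediate-early and MAPK output genes 3 and 3 (4 and 3). Of 11 BCL2 family genes 2 rose and 0 fell (3 and 0), of 23 genes of glycolysis and hypoxia 2 and 5 (2 and 5), and of 26 nuclear genes of oxidative phosphorylation 0 and 0 (0 and 0). Of 8 luminal epithelial markers 1 rose and 0 fell (1 and 0), and of 8 fibroblast markers 1 and 0 (0 and 0). Actb, a common reference gene, fell by 0.43 ± 0.08 (adjusted p = 0.00161) and Gapdh had -0.43 ± 0.24 (adjusted p = 0.247).

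**Figure D2:**
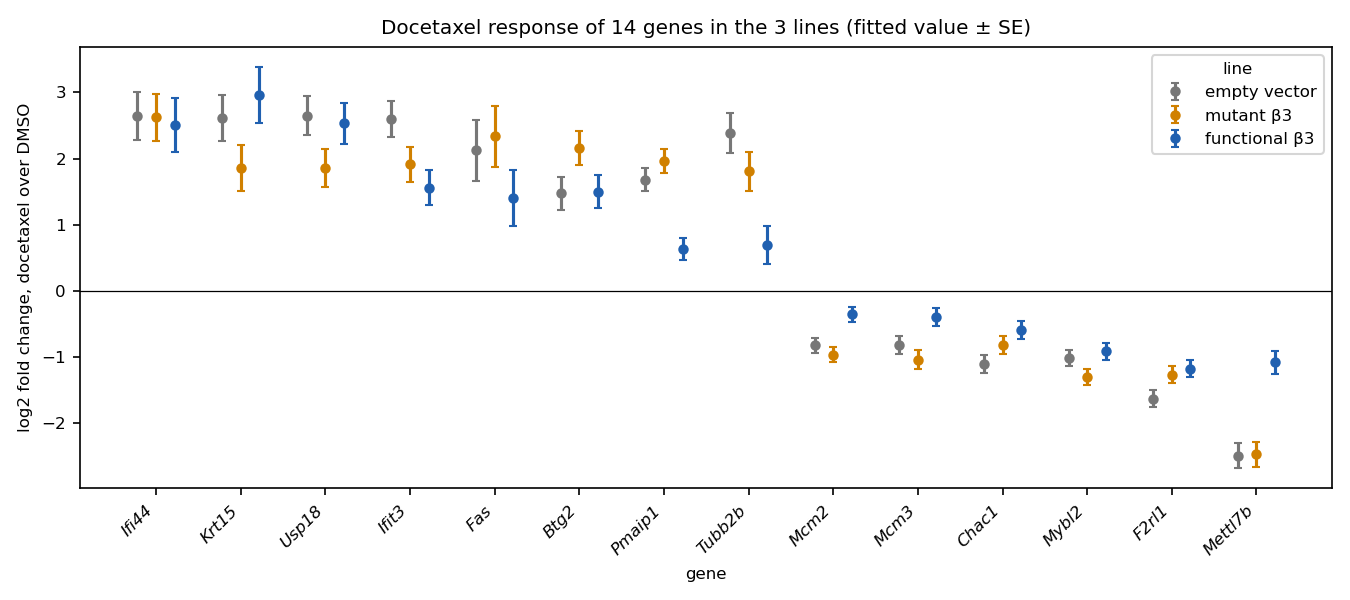
Log2 fold change of 14 named genes, docetaxel against DMSO, in each of the 3 lines (points; bars are the SE of the edgeR fit, 3 against 3 libraries; empty vector is pMx, mutant β3 is Δβ3, functional β3 is hβ3). Interferon genes and p53 targets lie above 0 and Mcm2, Mcm3, Chac1, Mybl2, F2rl1 and Mettl7b below 0 in each line.

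Within single lines most called genes had the same direction in the other lines. In pMx, 440 genes changed, 233 upward and 207 downward (2626 with 16 libraries, 440 of them shared). Usp18 rose by 2.65 ± 0.30, Dmp1, an extracellular phosphoprotein of bone, by 2.79 ± 0.45, and Trp53inp1, a p53 target, by 3.08 ± 0.76, while Mettl7b stood at -2.49 ± 0.19. Of these 440 genes 438 had the same sign in Δβ3 and 420 in hβ3, and of the 834 genes called in Δβ3 760 had the same sign in hβ3. With 16 libraries it was 2278 of the 2626 genes called in pMx that had the same sign in hβ3. The median absolute log2 change of the 440 was 0.907 in pMx, where they were selected, 0.775 in Δβ3 and 0.483 in hβ3. Interferon response genes rose in 18 of 28 cases (23 adjusted over the list alone), and genes of DNA replication and S phase fell in 13 of 28 (19 adjusted over the list alone), with medians of 1.68 and -0.82 (adjusted p = 0.00999 and 0.0491 with an estimated correlation). The call of Trp53inp1 was lost without any 1 of 8 single libraries (adjusted p up to 0.187, without pMx DMSO culture 2), and the pMx count ran from 151 without pMx DMSO culture 2 to 1205 without Δβ3 docetaxel culture 2.

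In Δβ3, 834 genes changed, 405 upward and 429 downward (1391 with 16 libraries, 615 of them shared). Mettl7b stood at -2.47 ± 0.19, Btg2 rose by 2.16 ± 0.26, Pmaip1 by 1.96 ± 0.18 and Plk2, a p53-induced kinase, by 1.24 ± 0.11. Calhm2 (4.21 ± 1.10), Fam26e (3.96 ± 0.81) and Celsr1 (3.85 ± 0.98) had the largest increases by the naming rule, and none was called with 16 libraries (adjusted p = 0.241, 0.0517 and 0.316). Ung and Ddx11, at -2.12 ± 0.51 and -1.91 ± 0.56, were not called there either (adjusted p = 0.102 and 0.165). Of 28 interferon genes 13 rose (21 adjusted over the list alone), with a median of 1.28 (adjusted p = 0.0762 with an estimated correlation, and 0.00987 with 16 libraries). Of 28 replication genes 15 fell (17 adjusted over the list alone), with a median of -0.79 (adjusted p = 0.0762 with an estimated correlation, and 0.00144 with 16 libraries). The median change of all genes was 0.11 in this line, a fit of the 6 Δβ3 libraries alone called 0 genes, and without Δβ3 docetaxel culture 1 there were 1675. Among the docetaxel comparisons within a line, the heart marker sum differed most in this one. Markers of fibroblasts had a median of 2.73 with 0 of 8 called (1 adjusted over the list alone), and 0.03 with 16 libraries.

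In hβ3, 141 genes changed, 112 upward and 29 downward (1539 with 16 libraries, 141 of them shared). Usp18 rose by 2.53 ± 0.30, Tcp11l2 by 2.29 ± 0.36 and Myh1, a muscle myosin, by 2.37 ± 0.41. F2rl1 stood at -1.18 ± 0.13 and Rgs16, a regulator of G protein signalling, at -1.15 ± 0.20. Of 28 interferon genes 7 rose (15 adjusted over the list alone), with a median of 1.07 (adjusted p = 0.0385 with an estimated correlation). Of 28 p53 targets 3 rose and 1, Plk2, fell by 0.51 ± 0.11 (12 and 1 adjusted over the list alone), with a median of 0.58 (adjusted p = 0.000215 with an estimated correlation). The call of Plk2 was lost without any 1 of the 6 hβ3 libraries (adjusted p between 0.0946 and 0.128). None of the 28 replication genes was called, also adjusted over the list alone, at a median of -0.37 (camera adjusted p = 3.7e-07, adjusted p = 0.234 with an estimated correlation), while 12 were called with 16 libraries. The BCL2 family had a median of 0.35, with 0 of 11 called over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00513, adjusted p = 0.0488 with an estimated correlation). Myh1 is also a marker of skeletal muscle. Its call was lost without hβ3 DMSO culture 3 (adjusted p = 0.0568) and that of Rgs16 without hβ3 docetaxel culture 1 (adjusted p = 0.0585). The hβ3 count ran from 62 without hβ3 DMSO culture 1 to 554 without Δβ3 docetaxel culture 2.

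Of the genes called in single lines, 64 rose and 15 fell in all 3, where independent lists would share 0.0717 and 0.0175. With 16 libraries these were 406 and 301 genes. The count of 79 ran from 39 without hβ3 docetaxel culture 3 to 275 without Δβ3 docetaxel culture 2, and was 0 with only the groups of each comparison in the fit. The 3 contrasts share no libraries.

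The second question was whether the response to docetaxel depends on integrin β3 and its signalling, as the difference between lines in that response. Plk2, a p53-induced kinase (chromosome 13, 110395046 to 110400844), rose from 24.0 CPM ± 1.56 (SD, n = 3) to 46.95 ± 1.37 in pMx and from 25.1 ± 2.59 to 59.2 ± 2.09 in Δβ3, and fell from 194.9 ± 5.97 to 137.2 ± 2.33 in hβ3. Its difference in response was -1.47 ± 0.15 (SE, log2) for hβ3 against pMx (adjusted p = 0.000312) and -1.74 ± 0.15 for hβ3 against Δβ3 (adjusted p = 2.7e-05). Apcdd1, an inhibitor of WNT signalling (chromosome 18, 62922231 to 62961179), went from 211.8 CPM ± 3.91 to 115.9 ± 5.35 in pMx, from 233.0 ± 20.9 to 130.1 ± 3.33 in Δβ3 and from 164.8 ± 10.6 to 187.5 ± 2.16 in hβ3. Its difference in response was 1.05 ± 0.14 against pMx (adjusted p = 0.00629) and 1.03 ± 0.14 against Δβ3 (adjusted p = 0.00897).

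Against Δβ3, S100a7a and Rgs2 also responded differently in hβ3. S100a7a, a calcium-binding protein of inflamed epithelia (chromosome 3, 90654017 to 90658669), went from 56.1 CPM ± 1.67 to 26.5 ± 2.60 in hβ3 and from 0.94 ± 0.198 to 3.41 ± 2.19 in Δβ3 (difference in response -2.86 ± 0.48, adjusted p = 0.0492, and -2.12 ± 0.34 with 16 libraries). Rgs2, a regulator of G protein signalling (chromosome 1, 143999338 to 144004161), went from 18.9 CPM ± 2.85 to 22.5 ± 2.63 in hβ3 and from 18.1 ± 1.10 to 50.8 ± 2.77 in Δβ3 (-1.24 ± 0.21, adjusted p = 0.0492).

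In all, 2 genes were called for hβ3 against pMx and 5 for hβ3 against Δβ3 (edgeR quasi-likelihood test), and the joint test over the 3 lines called 2, Apcdd1 and Plk2. With 16 libraries the counts were 284, 73 and 186, with all 5 genes called in the same direction, and DESeq2 called 27, 37 and 38. For Δβ3 against pMx edgeR called 0 genes, with 16 libraries also 0, DESeq2 0 and edgeR with RLE factors 0. An unadjusted edgeR p under 0.05 was reached by 520 of the 12145 tested genes, and by 353 of 12356 with 16 libraries. Both are smaller shares than the 0.05 that would arise without any difference. The calls of S100a7a and Rgs2 were lost with RLE factors (adjusted p = 0.0649 for both) and without most single libraries, and that of Apcdd1 against Δβ3 without hβ3 DMSO culture 1 (adjusted p = 0.0605) or hβ3 docetaxel culture 1 (adjusted p = 0.0529). The count against pMx was 7 without Δβ3 DMSO culture 1 and 21 without Δβ3 docetaxel culture 2, and the count against Δβ3 ran from 1 without hβ3 DMSO culture 1 to 9 without Δβ3 docetaxel culture 2.

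No list call of an interaction held with an estimated correlation over 18 libraries. Genes of DNA replication and S phase had a median difference in response of 0.44 for hβ3 against pMx, with 0 of 28 called, also adjusted over the list alone (camera adjusted p = 1.8e-07, adjusted p = 0.269 with an estimated correlation, and 0.0332 with 16 libraries). Against Δβ3 the median was 0.53, with 0 of 28 called and 3 adjusted over the list alone (camera adjusted p = 2.8e-07, adjusted p = 0.469 with an estimated correlation, and 0.0482 with 16 libraries). Interferon response genes had a median of -0.37 for hβ3 against pMx, with 0 of 28 called, also adjusted over the list alone (camera adjusted p = 1.2e-06, adjusted p = 0.269 with an estimated correlation). For Δβ3 against pMx, nuclear genes of oxidative phosphorylation had a median of 0.90 over 18 libraries and 0.03 over the 16 libraries without the 2 that held most heart transcripts.

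**Figure D3:**
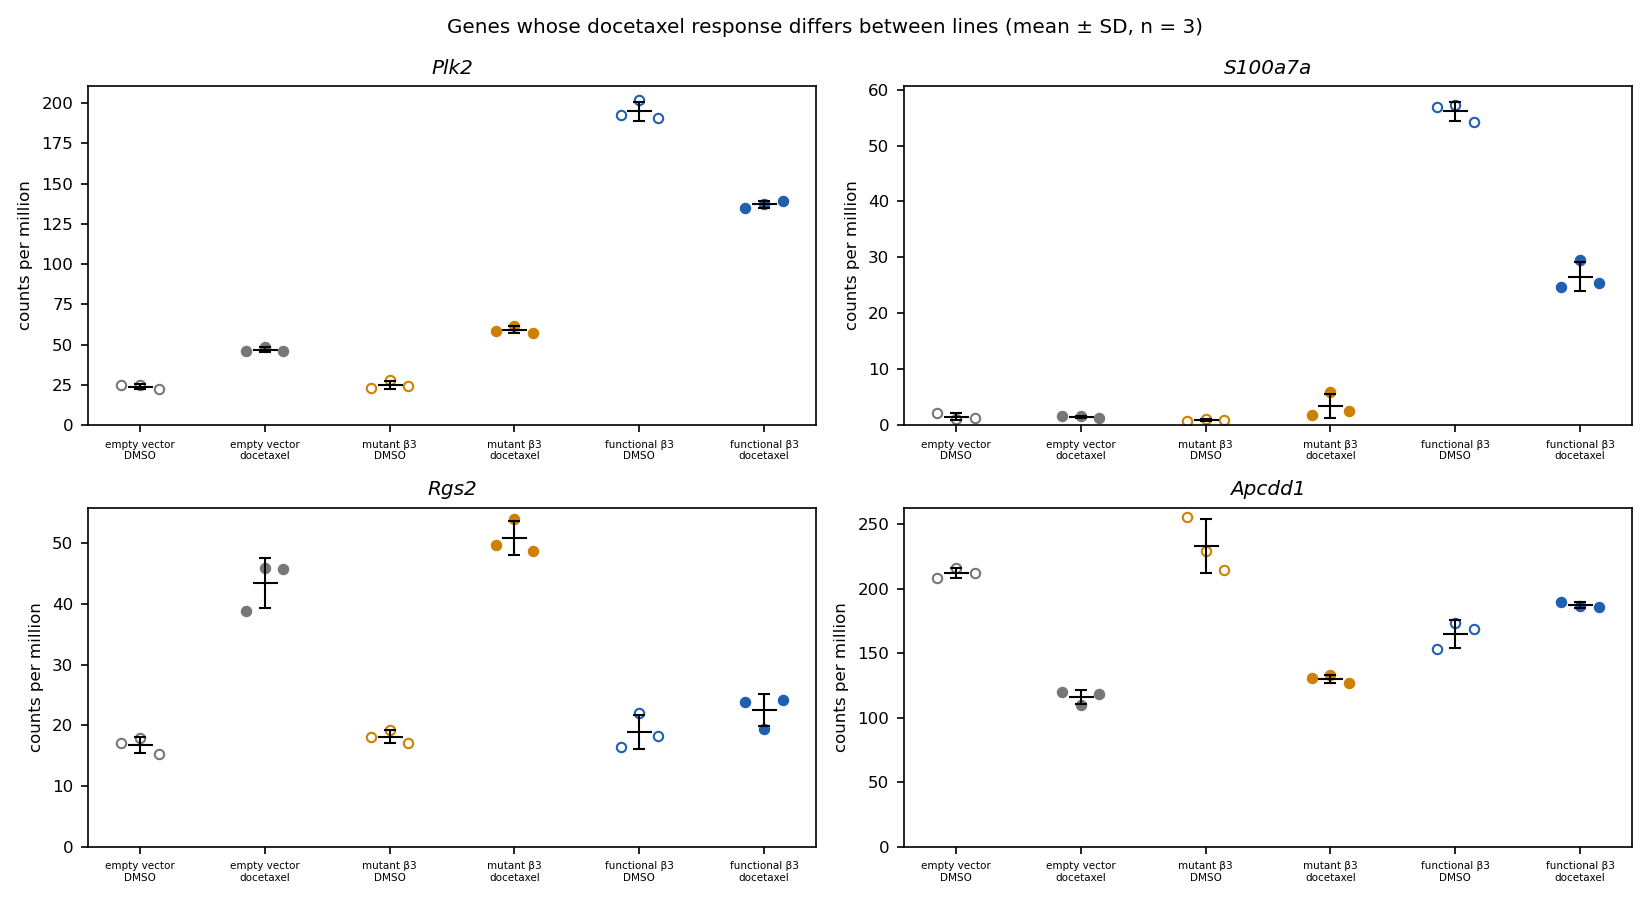
Level (CPM) of Plk2, S100a7a, Rgs2 and Apcdd1 in each library, with mean and SD of 3 cultures, in DMSO (open) and docetaxel (filled) for the lines pMx (empty vector), Δβ3 (mutant β3) and hβ3 (functional β3). Plk2 goes from 194.9 to 137.2 CPM in hβ3 and from 25.1 to 59.2 CPM in Δβ3.

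The third comparison set the lines side by side in DMSO, to ask what functional integrin β3 changes without the drug. The hβ3 line had a different expression pattern from both other lines. Wnt7a, a secreted WNT ligand (chromosome 6, 91363981 to 91411363), had 129.9 CPM ± 7.52 (SD, n = 3) in hβ3, 0.443 ± 0.190 in pMx and 0.755 ± 0.811 in Δβ3. Tgfa, a ligand of the EGF receptor (chromosome 6, 86195223 to 86275719), had 33.2 CPM ± 1.30, 1.05 ± 0.573 and 1.52 ± 0.128 in the same order. Msln, the surface protein mesothelin (chromosome 17, 25748613 to 25754378), had 6.52 CPM ± 0.608, 0.157 ± 0.0895 and 0.0617 ± 0.0538. Inhbb, a subunit of activin B (chromosome 1, 119415465 to 119422248), was lower, with 4.16 CPM ± 0.995 in hβ3, 101.3 ± 8.84 in pMx and 188.3 ± 110.1 in Δβ3.

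In hβ3 against pMx 1095 genes differed, 593 higher and 502 lower (edgeR quasi-likelihood test), and with 16 libraries 3312, with 1095 shared. The log2 difference was 8.16 ± 1.27 (SE) for Wnt7a (adjusted p = 0.00105), 4.95 ± 0.52 for Tgfa and 6.46 ± 0.76 for Slc25a48, a mitochondrial carrier. It was 5.20 ± 0.38 for S100a7a and 3.81 ± 0.64 for Ptprq, a receptor phosphatase. Mgp, an inhibitor of calcification, stood at -4.46 ± 0.36, Dmp1 at -4.82 ± 0.59, Mmp3, the protease stromelysin 1, at -4.05 ± 0.33 and Tnfrsf11b, the RANKL decoy receptor osteoprotegerin, at -3.98 ± 0.56. Krt15 stood at -3.90 ± 0.42, Scara5, a ferritin receptor, at -4.13 ± 0.26, and Inhbb at -4.60 ± 0.32 (adjusted p = 7.3e-08). Leaving out Δβ3 docetaxel culture 2 raised the count to 1959, and leaving out pMx DMSO cultures 1 or 2 or hβ3 DMSO culture 3 lowered it to 719, 714 and 699.

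In hβ3 against Δβ3 1594 genes differed, 761 higher and 833 lower, and with 16 libraries 2880, with 1524 shared. Wnt7a differed by 7.48 ± 1.23, Tgfa by 4.43 ± 0.51 and Vgll3, a cofactor of TEAD transcription factors, by 3.73 ± 0.51, while Inhbb stood at -5.50 ± 0.33, Mgp at -4.77 ± 0.36 and Rhov, a small GTPase, at -5.03 ± 0.49. The count was 2857 without Δβ3 docetaxel culture 2 and 962 without hβ3 DMSO culture 3. In the same direction against both lines, 457 genes were higher and 425 lower, where independent lists would share 37.2 and 34.4. Both comparisons use the same hβ3 libraries. In 20 simulations of groups without any change, at most 1 gene was called for hβ3 against pMx (2 with 16 libraries). At most 0 genes were shared with hβ3 against Δβ3 (1 with 16 libraries), whose own calls were not counted. Genes that truly differ from 1 of the lines were not simulated. With 16 libraries 1155 genes were higher and 1190 lower against both lines.

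Of 28 p53 targets 5 were higher and 0 lower in hβ3 than in pMx (8 and 0 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.000652, adjusted p = 0.018 with an estimated correlation). Plk2 differed by 3.02 ± 0.11 and Pmaip1 by 2.55 ± 0.18. Of 28 interferon response genes 5 were lower and 0 higher (6 and 0 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 0.00043, adjusted p = 0.477 with an estimated correlation), and Ifi44 stood at -2.74 ± 0.41 and Usp18 at -1.88 ± 0.30. Of 19 SRF and YAP targets 4 were higher and 0 lower (5 and 0 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.00043, adjusted p = 0.477 with an estimated correlation, and 0.0374 with 16 libraries). They included Cyr61, a matrix protein, at 2.50 ± 0.23 and Ajuba, a scaffold of cell junctions, at 1.47 ± 0.22. Of 12 tubulins 2 were higher (3 adjusted over the list alone), Tubb3 by 1.31 ± 0.15 and Tubb2b by 1.99 ± 0.30, with 0 lower (camera adjusted p = 0.0473, adjusted p = 0.477 with an estimated correlation). Of 25 genes of the amino acid and ATF4 response 5 were higher and 1 lower (6 and 1 adjusted over the list alone), with Chac1 at 1.34 ± 0.14 and Ddit4, an inhibitor of mTORC1, at -0.95 ± 0.21 (camera adjusted p = 0.0336, adjusted p = 0.477 with an estimated correlation). Rn45s took 10.9% to 33.0% of counts in the hβ3 DMSO libraries and 8.36% to 9.81% in those of pMx.

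Against Δβ3, 10 of 21 immediate-early and MAPK output genes were lower in hβ3 and 2 higher (11 and 2 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 0.00043, adjusted p = 0.503 with an estimated correlation). Fos stood at -3.22 ± 0.41, Egr1 at -2.69 ± 0.40 and Dusp2, a MAPK phosphatase, at -3.16 ± 0.24. Of 28 interferon response genes 7 were lower and 0 higher (12 and 0 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 0.00043, adjusted p = 0.503 with an estimated correlation). Of 28 p53 targets 5 were higher and 0 lower (6 and 1 adjusted over the list alone; adjusted p = 0.249 with an estimated correlation), and of 19 SRF and YAP targets 4 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.682 with an estimated correlation). Of 25 genes of the amino acid and ATF4 response 6 were higher and 2 lower (12 and 3 adjusted over the list alone; adjusted p = 0.503 with an estimated correlation). Of 25 extracellular matrix and mesenchymal genes 7 were lower and 4 higher (10 and 4 adjusted over the list alone), among them Col6a1, a collagen VI chain, at -3.38 ± 0.26. That list had a median of -0.69 with 18 libraries (adjusted p = 0.503 with an estimated correlation) and -0.19 with the 16 libraries that exclude the most heart transcripts, where it was not called (camera adjusted p = 0.231).

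**Figure D4:**
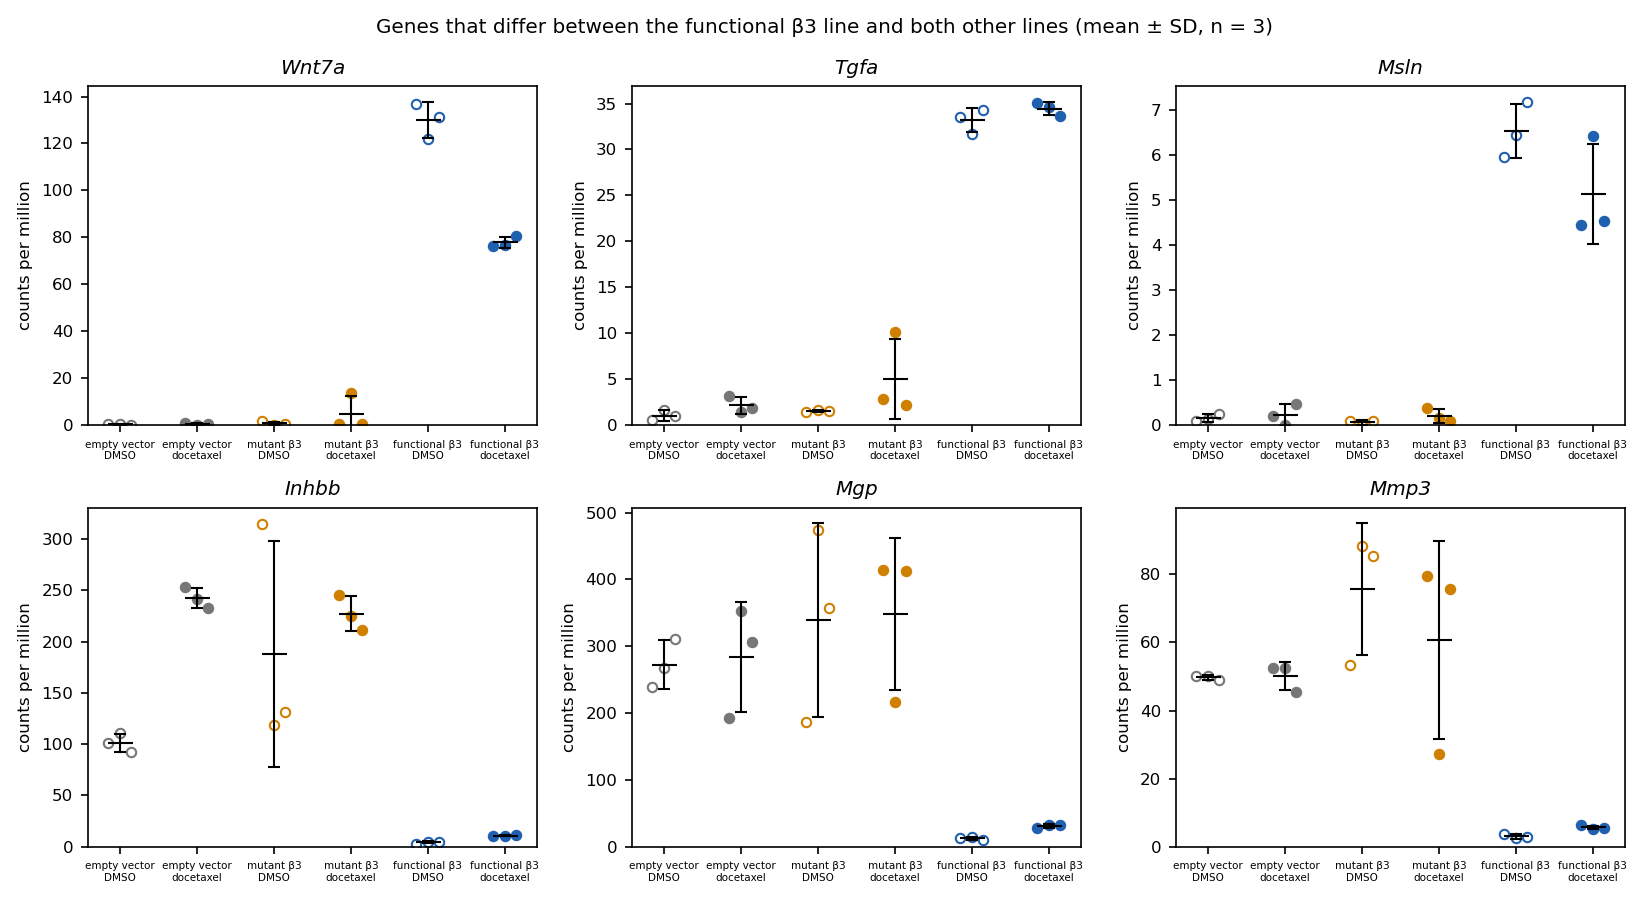
Level (CPM) of Wnt7a, Tgfa, Msln, Inhbb, Mgp and Mmp3 in each library, with mean and SD of 3 cultures, in DMSO (open) and docetaxel (filled) for the lines pMx (empty vector), Δβ3 (mutant β3) and hβ3 (functional β3). In DMSO, Wnt7a has 129.9 CPM in hβ3 and 0.443 CPM in pMx, and Inhbb 4.16 and 101.3 CPM.

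Between Δβ3 and pMx in DMSO, 5 genes differed. Itgb3 was higher in Δβ3 by a log2 difference of 6.66 ± 0.56 (SE, 3 against 3 libraries), and so were the immediate-early genes Egr1 (chromosome 18, 34859823 to 34864984), by 3.03 ± 0.41, Fos (chromosome 12, 85473890 to 85477273), by 2.89 ± 0.41, and Ier2, by 1.30 ± 0.21. Igsf11, an adhesion protein of the immunoglobulin family, was lower at -1.16 ± 0.15. Egr1 had 133.0 CPM ± 20.3 (SD, n = 3) in Δβ3, 16.3 ± 1.78 in pMx and 20.6 ± 3.99 in hβ3. The adjusted p was 9.9e-05 for Itgb3, 0.00703 for Egr1 and for Fos, 0.0264 for Ier2 and 0.00338 for Igsf11 (edgeR quasi-likelihood test). Of 21 immediate-early and MAPK output genes 3 were higher and 0 lower (9 and 0 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 4.3e-09, adjusted p = 0.236 with an estimated correlation, and 0.00586 with 16 libraries). With 16 libraries 41 genes were called, 5 of them shared. The call of Egr1 was lost without any 1 of the 3 pMx DMSO cultures (adjusted p = 0.118, 0.0941 and 0.0672), that of Fos without pMx DMSO culture 3 (adjusted p = 0.0565), and that of Ier2 without any 1 of 10 single libraries (adjusted p up to 0.329, without pMx DMSO culture 2). The count ran from 2 without pMx DMSO culture 3 to 20 without Δβ3 docetaxel culture 2.

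In docetaxel the lines were compared again, to see which differences stood after treatment. Against pMx, hβ3 had 1027 genes that differed, 562 higher and 465 lower (3378 with 16 libraries, 1026 shared). Wnt7a was higher by a log2 difference of 7.17 ± 1.23 (SE) and Slc25a48 by 5.31 ± 0.76, while Dmp1 stood at -6.74 ± 0.58 and Nlrp10, an NLR family protein, at -5.06 ± 0.54. Of 28 interferon response genes 12 were lower and 0 higher (20 and 0 adjusted over the list alone), with a median of -1.19 (camera adjusted p = 5.6e-13, adjusted p = 0.0766 with an estimated correlation). Of 28 genes of DNA replication and S phase 4 were higher and 0 lower, also adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.00027, adjusted p = 0.38 with an estimated correlation), among them Rrm2, a subunit of ribonucleotide reductase, by 0.90 ± 0.15. Of 25 genes of the amino acid and ATF4 response 9 were higher and 0 lower (10 and 1 adjusted over the list alone), with Chac1 at 1.85 ± 0.14 (adjusted p = 0.0766 with an estimated correlation). In all, 11 lists were called by camera and 0 with an estimated correlation. The count of genes was 1580 and 1964 without Δβ3 DMSO culture 1 and Δβ3 docetaxel culture 2, and between 572 and 649 without pMx docetaxel cultures 1 or 3 or any 1 of the hβ3 docetaxel cultures.

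Against Δβ3 in docetaxel, hβ3 had 1223 genes that differed, 532 higher and 691 lower (2460 with 16 libraries, 1093 shared). Slc25a48 was higher by 4.47 ± 0.73, Msln by 4.45 ± 0.63 and Wnt7a by 4.13 ± 1.02 (7.44 with 16 libraries), while Dmp1 stood at -6.48 ± 0.57. Ldhd and Lrrc32, at -6.14 ± 1.70 and -6.07 ± 1.79, were not called with 16 libraries (adjusted p = 0.189 and 0.105). Of 21 immediate-early and MAPK output genes 8 were lower and 1 higher (13 and 1 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 0.000128, adjusted p = 0.278 with an estimated correlation, and 0.0347 with 16 libraries). Of 26 nuclear genes of oxidative phosphorylation 1 was lower and 0 higher (0 adjusted over the list alone), and the median of -0.80 became 0.20 with the 16 libraries that exclude the most heart transcripts (adjusted p = 0.664 with an estimated correlation over 18). Also here 11 lists were called by camera and 0 with an estimated correlation. The count of genes was 2656, 2187 and 1982 without Δβ3 docetaxel cultures 1 or 3 or Δβ3 DMSO culture 1, and 604, 591 and 667 without hβ3 docetaxel cultures 1, 2 and 3. Against both other lines, 382 genes were higher and 357 lower in hβ3, where independent lists would share 24.6 and 26.5 (1031 higher and 1029 lower with 16 libraries). As in DMSO, the hβ3 libraries are shared. The simulations without any change called 0 genes for hβ3 against pMx, or at most 2 with 16 libraries. At most 1 gene was shared with hβ3 against Δβ3, whose own calls were not counted.

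Between Δβ3 and pMx in docetaxel 3 genes differed, Itgb3 by a log2 difference of 7.12 ± 0.59 (SE), Fos by 2.34 ± 0.38 (adjusted p = 0.0421, lost without any 1 of 14 single libraries) and Igsf11 by -1.12 ± 0.15 (adjusted p = 0.00426). With 16 libraries 56 genes were called, 3 of them shared. Of 21 immediate-early and MAPK output genes 1 was higher (4 adjusted over the list alone), with a median of 0.30 (camera adjusted p = 0.021, adjusted p = 0.725 with an estimated correlation, and 0.0162 with 16 libraries). Of 26 nuclear genes of oxidative phosphorylation 0 were called over all genes and 22 were higher adjusted over the list alone, with a median of 1.13 (camera adjusted p = 6.1e-08, adjusted p = 0.725 with an estimated correlation). That median was 0.05 with the 16 libraries that exclude the most heart transcripts, where 0 of 26 were called. The count of genes was 1 without Δβ3 docetaxel culture 1, where the call of Igsf11 was lost (adjusted p = 0.0682), and 8 without Δβ3 docetaxel culture 2.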

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

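The tests of the 2 heart-rich libraries, of the called interaction genes and of Rgs2 were chosen only after the result was seen; the test over all genes responding in pMx was written before.

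Plk2 and Apcdd1 responded to docetaxel differently in hβ3 than in both other lines, which the interaction test called. The difference in response was -1.473 for Plk2 and 1.055 for Apcdd1 against pMx, and -1.742 and 1.027 against Δβ3. Against Δβ3 the same test also called Rgs2 (-1.236) and S100a7a (-2.864). Without the 2 heart-rich libraries all 5 of the 5 called genes stayed called in the same direction, so these libraries do not explain the calls.

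A difference between the lines before docetaxel may explain part of the pattern, because a gene that is already high may have less room to rise. If hβ3 cells stood closer to the docetaxel state before treatment, their DMSO difference from Δβ3 would rise with the docetaxel response of pMx, which shares no library with it. Over the 2626 genes called in pMx with 16 libraries the correlation was -0.359 (95% interval -0.403 to -0.314). The interval comes from resampling genes as if they were independent, so it leaves out the spread between cultures and between lines. In these cultures the negative correlation argues against the explanation as the general trend of that set. It does not exclude the explanation for single genes, because 37.05% of the set, Plk2 among them, had the same sign in both. Of the 5 called genes, 4 (Plk2, S100a7a and Apcdd1 among them) had a called difference in DMSO opposite to their interaction. The shared DMSO libraries mean that this alone cannot be told from a true difference in response. In hβ3, however, docetaxel lowered Plk2 by a log2 change of 0.51 ± 0.11 (SE; 0.49 ± 0.07 with 16 libraries). By the levels given above, S100a7a fell there too. Less room to rise would give a smaller rise and not a fall, which argues against that explanation for these 2 genes. For Apcdd1 the DMSO difference between hβ3 and Δβ3 was -0.50 (95% interval -0.70 to -0.30), against an interaction of 1.027. By the levels given above, hβ3 was lower than Δβ3 in DMSO and higher in docetaxel. A limit set by the DMSO level would not lead to such a crossing, which argues against the explanation for Apcdd1. For Rgs2 the DMSO difference between hβ3 and Δβ3 was 0.0603 (95% interval -0.23 to 0.35), so the explanation is excluded there.

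Regrouping the libraries gave as many interaction calls in some draws. Of 25 splits, 2 had at least the 2 calls of hβ3 against pMx (the real grouping among them; highest other 46), and 3 had at least the 5 calls of hβ3 against Δβ3 (highest other 192). Exchanging line labels within 1 treatment can turn differences between lines into interactions: the draws with 46 and 192 calls each moved 6 DMSO and 2 docetaxel labels, and the 1 other large draw, with 155, moved 4 DMSO and 0 docetaxel labels. Other draws that moved 4 DMSO and 0 docetaxel labels gave 0 calls, against pMx and against Δβ3. Draws with exchanged labels do not stand for an absence of interaction, so for both counts the splits leave chance open. For Δβ3 against pMx the splits decide nothing, because the count found is 0 and all 25 splits reach it by construction (highest other 1). For the joint test, 1 of 25 splits, the real grouping, reached 2 calls (highest other 0). Every other draw mixed libraries of lines that differ in many genes, which widens the spread within groups, so this test leaves chance open.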

How the results depend on the processing

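The 16-library fits, the counts without Rn45s, the single-model test and the omission of libraries from other groups were tests chosen only after the result was seen; the others were chosen before.

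DESeq2 called more genes. It had 836 for docetaxel in pMx, 1614 in Δβ3 and 385 in hβ3, with 193 shared by the 3 lines. For the interactions it had 27 (hβ3 against pMx), 37 (hβ3 against Δβ3) and 38 (joint), and for Δβ3 against pMx 33 in DMSO and 7 in docetaxel. RLE factors left 3 calls for the interaction of hβ3 with Δβ3, and the counts without Rn45s also left 3. No low-count filter left 47 docetaxel calls shared by the 3 lines. Single transcript models gave 1 call for each interaction of hβ3 and 1 for the joint test.

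With only the groups of the comparison in the fit, docetaxel called 2239 genes in pMx, 0 in Δβ3 and 1388 in hβ3, with 0 shared. The interactions had 213 calls (hβ3 against pMx) and 1 (hβ3 against Δβ3). The line pairs hβ3 against pMx, hβ3 against Δβ3 and Δβ3 against pMx had 2835, 830 and 2 in DMSO and 3328, 294 and 0 in docetaxel. The fits with more calls leave out the Δβ3 libraries, and those with fewer hold 1 or both of the heart-rich ones among fewer libraries.

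Without the 2 heart-rich libraries docetaxel called 3715 genes as the mean, 2626 in pMx, 1391 in Δβ3 and 1539 in hβ3, with 707 shared. The interactions had 284 (hβ3 against pMx), 73 (hβ3 against Δβ3) and 186 (joint). The line pairs had 3312, 2880 and 41 in DMSO and 3378, 2460 and 56 in docetaxel, with 2345 for hβ3 against both lines in DMSO. List calls became 8 (interaction of hβ3 with Δβ3), 0 (interaction of Δβ3 with pMx) and 4 (Δβ3 against pMx in DMSO). With the heart transcript level as a covariate added, the counts were 4014, 2908, 1723 and 1812 for docetaxel, with 828 shared. The interactions had 663, 137, 1 (Δβ3 against pMx) and 423 (joint). The line pairs had 2957, 3158 and 43 in DMSO and 3584, 2768 and 73 in docetaxel, with 2351 against both lines.

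Camera with an estimated correlation called 4 lists for the mean, 4 in pMx, 2 in Δβ3 and 3 in hβ3, 0 for each interaction, 1 for hβ3 against pMx in DMSO and 0 for each other line pair. With the preset correlation these were 8, 7, 8, 8, then 7, 3 and 5 for the interactions, 5, 6 and 1 in DMSO and 11, 11 and 4 in docetaxel. Fry called 14 for the mean, 13 in Δβ3, 5 in hβ3, 0 for each interaction and 3 for Δβ3 against pMx in DMSO.

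Leaving out single libraries gave 1421 to 2631 docetaxel calls for the mean, 151 to 1205 in pMx, 578 to 1675 in Δβ3 and 62 to 554 in hβ3, with 39 to 275 shared. The interactions ran from 2 to 21 (hβ3 against pMx), 1 to 9 (hβ3 against Δβ3), 0 to 0 (Δβ3 against pMx) and 1 to 18 (joint). In DMSO the pairs ran from 699 to 1959, 962 to 2857 and 2 to 20, with 576 to 1543 for hβ3 against both lines, and in docetaxel from 572 to 1964, 591 to 2656 and 1 to 8. List calls ran from 8 to 10 for the mean, 6 to 9 in pMx, 6 to 9 in Δβ3 and 8 to 9 in hβ3, from 4 to 8, 3 to 6 and 1 to 6 for the interactions, from 3 to 6, 2 to 6 and 1 to 3 in DMSO and from 9 to 12, 7 to 13 and 3 to 8 in docetaxel. For the changes not tied to the heart-rich libraries the cause was not tested.

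The labels do not say whether culture numbers pair the samples, and the values do not settle it. Of 45 correlations between cultures of the same number 18 exceeded 0.1 (from -0.53 to 0.46). In 1 of 15 pairs of groups, pMx docetaxel with Δβ3 DMSO, all 3 did (0.43, 0.27 and 0.26). With 3 numbers to choose from, 10 of 18 libraries were closest to their own. With the replicate block the interaction of hβ3 with Δβ3 had 3 calls.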

Other observations

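The heart tests, the test of chromosomes with a median near 0 and the fit with the Rn45s covariate were tests chosen only after the result was seen; the Rn45s share test was written before.

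Heart muscle transcripts were high in 1 library of each Δβ3 group, and RNA from heart tissue mixed into the libraries is 1 explanation. The log2 counts of the markers in Δβ3 docetaxel culture 2 had a correlation of 0.962 with pMx docetaxel culture 1 and 0.995 with Δβ3 DMSO culture 1. RNA from heart tissue would give such high values, so they meet the prediction of that explanation. The markers ran from 0 counts for Tnnt2 in all of these libraries to 62649 for Actc1 in Δβ3 docetaxel culture 2. So wide a range can give a high correlation whatever the origin of the transcripts, so this test alone does not decide. Heart RNA from several sources could give such values as well, so the test cannot tell 1 source from several. Expression by the cells in response to docetaxel or the mutant integrin is excluded, because culture 2 had 108.5 times the marker level of the highest other culture of its group. The summed level of skeletal muscle markers was not raised in culture 2, at a ratio of 0.974. That sum cannot exclude skeletal muscle RNA, because Myh1 alone gave 199 of its 266 counts in culture 1 of the group. Among single markers, Neb had 71 counts in culture 2, against 5 and 10 in cultures 1 and 3. The CPM of Myh1, Mylpf, Actn3 and Tnnc2 in culture 2 did not exceed that of both other cultures. Where the heart RNA came from was not tested.

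Genes differed between hβ3 and both other lines in DMSO, and with 1 line per construct, selection of that line could act like an effect of the integrin, which these libraries cannot separate. Gain or loss of whole chromosomes cannot be told, as the largest median, that of chromosome 19, was 0.208 against pMx with 16 libraries. Chromosome 19 had 108 called genes higher and 23 lower and chromosome 7 had 64 and 162, while chromosome 2 had 97 and 106. On the 11 chromosomes with a median within 0.05 of 0, 28.3% of genes (1818 of 6419) were called. A gain or loss of those whole chromosomes does not account for these calls. Effects of other chromosomes or of chromosome parts were not tested. A fit with the Rn45s share as covariate kept a median of 95.6% of the difference over the 2345 genes, which argues against the Rn45s share as the cause for that set. Of these genes 1590 stayed called against pMx in the same direction, so the share is excluded as the whole cause for those 1590. For single genes among the others it stays open. Of 803 genes called without hβ3 DMSO culture 2, 792 (98.6%) had the same direction in that library, at a median of 0.86 times the fitted change. That library had 10.9% Rn45s, against 8.36% to 9.81% in the pMx DMSO libraries. Both sides of this test use the same pMx libraries, so it decides nothing alone. Against 882 genes in common to both comparisons (2345 with 16 libraries), simulated groups without any change shared at most 0 (1 with 16), but genes that truly differ from 1 line were not simulated, so for those the effect of the shared hβ3 libraries stays open.

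Regrouping within lines argues against chance for the mean docetaxel response, where 1 of 100 splits, the real grouping, reached 1891 calls (highest other 802). These splits were a random sample of those possible, so chance is made unlikely and not excluded. With 3 against 3 libraries there are 10 splits, which cannot reach a probability under 0.05. In those 10 splits the real grouping was the only 1 to reach its count, with a highest other of 0, for docetaxel in pMx (440) and hβ3 (141) and for the 6 line pairs (1095, 1594 and 5 in DMSO, 1027, 1223 and 3 in docetaxel). For docetaxel in Δβ3, 5 of 10 splits reached at least 834 calls (highest other 1670), and those with more calls all put Δβ3 DMSO culture 1 and Δβ3 docetaxel culture 2 in the same part.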
